A study of Mus musculus with 2 samples.

How the data were processed

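Gene expression and zone tags were measured in single cells from 1 pool of tumors of the diphtheria toxin group, as a gene expression library and a tag library. Values in the deposited matrix are counts, namely UMIs per feature and barcode with no normalization. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 4.0.0. The deposited matrix is unfiltered and holds 6794880 barcodes, 31056 gene rows and 3 tags, with 3 reporter sequences among the gene rows (mCherry, mVenus and dsredexpress1). How the submitters called cells, counted tags and named cell types is not stated.

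Barcodes with at least 500 genes (4801) and at most 10% mitochondrial UMIs (4519) were taken. Scrublet, run in scanpy 1.11.5 with an expected rate of 3.62%, marked 1 of them (0.0221%). It is treated as not having worked, so doublets remain among the 4518 kept barcodes and are described through lineage markers instead. Counts were scaled to 10000 per barcode and log transformed, and 2000 variable genes were chosen without mitochondrial genes, the reporters and the 214 genes of the 18 lists (4 of which are not among the features). These genes were scaled (values limited to 10), reduced to 30 principal components and joined to 15 neighbours, and clusters were called with leiden at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, anndata 0.12.19). Clusters were named from fixed markers of 22 classes: a name needed at least 3 detected markers and markers of that class among the 10 genes with the highest fold. Leaving list genes out keeps values of those genes from defining the clusters directly, but genes that vary with them remain: the histone genes Hist1h1a and Hist1h1b, outside the lists, were among the leading genes of the macrophage-like cluster. The markers and the lists share 4 genes (Vcan, F13a1, Fn1 and Eomes), of which Vcan was among the leading genes that named a cluster. Names of the classes were given after the clusters were seen.

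Mixed barcodes were defined after the data were seen as those with at least 3 marker genes and 5 UMIs of at least 2 of 5 lineages (T cell, phagocyte, neutrophil, pDC and melanoma). Abundant or widely used markers (Apoe, S100a8, S100a9, Tcf4 and Runx2) were left out. A cluster with 50% or more mixed barcodes is called mixed, and 4 of 18 clusters were.

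Gene levels are summed UMIs per 10000 gene UMIs of a class with exact Poisson intervals, and shares of barcodes carry exact (Clopper-Pearson) binomial intervals. Shares of barcodes with a UMI were compared after thinning to 1000 UMIs, leaving out shallower barcodes. A gene with no UMI is given the limit that 3 UMIs would set. Classes were compared by ratios of these sums with an exact interval from the conditional binomial distribution. With 1 library per class there is no test across samples, no p-value and no standard error. Intervals at the 95% level cover counting error only, and counts of genes describe this library.

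The lists and the rule for named genes were fixed before the data were examined. Mrc1, Cxcl9, Cxcl10, Xcl1, Ifng, Flt3l, Csf1 and Cxcr3 were computed for every class, whatever their values. The text gives these values for part of the classes. For each comparison, list genes with at least 20 UMIs over both sides, at least 2-fold apart and with an interval that excludes 1 could be named, up to the 15 largest ratios in each direction. For tags, genes outside the lists could be named with at least 50 UMIs, a UMI in at least 5% of barcodes on one side and an interval beyond 1.5 either way, up to 10 in each direction. The rule also set list members with the most UMIs as examples, but the examples given are from the genes it names by ratio. Other list members, and those named for the stratified comparison, were chosen after their values were seen. The percentile of each list's median among 10000 random lists matched on mean expression was computed as a description. Coordinates are from GENCODE M21 by gene identifier.

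Log tag counts were centred over barcodes, and a tag was called in barcodes with at least 10 tag UMIs whose leading tag was at least 2 times the second. Which tag marks which zone is not stated, so no zone is named. Of the tag UMIs, 34.7% lay in barcodes under 100 gene UMIs. The planned comparison of zones within a class needed 50 barcodes in both tags, which none of its classes reached at this ratio of 2. It was replaced, after the data were seen, by neutrophil-like barcodes (ZC1 against ZC2) and by pooled phagocytes (ZC1 against ZC5), the latter also stratified by class with the Mantel-Haenszel ratio and an approximate interval from the Greenland-Robins variance.

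The comparisons were tested on simulated sums with 200 genes changed by 3-fold or 6-fold. At 3-fold, 98.0% of changed genes were called in the right direction for macrophage-like against monocyte-like barcodes, 86.7% for CD8 T-like against NK-like, 81.0% for the neutrophil tags and 95.8% for the stratified comparison. At 6-fold all were. Of unchanged genes 0.470%, 1.81%, 1.69% and 1.09% were called. The simulated sums were Poisson draws with no further spread between barcodes, as the intervals assume. These rates therefore do not give the rate of false calls in the real data.

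Alternatives fixed before the data were examined changed the minimum of genes (200 and 1000), the mitochondrial limit (5% and 20%), the removal of marked doublets, the leiden resolution (0.5 and 2), the thinning depth (2000 UMIs and none) and the tag call (ratios of 1.5 and 4, and 30 tag UMIs). In settings that were clustered again, each cluster took the name of the class most of its barcodes had. After the data were seen, 6 more were added: leaving out mixed barcodes, at least 20 marker UMIs per lineage, stratification by class, this stratification without mixed barcodes, and the class comparisons at both other leiden resolutions. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 drew the figures.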

Results

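The data are 1 single-cell library from 1 pool of mouse tumors, read as a gene expression library and a tag library of the same barcodes. The tumors came from B78chOVA cells, a melanoma line that carries the mCherry protein and ovalbumin. The hosts were Csf1rCre; Mrc1-LSL-Venus-DTR mice, in which cells with Cre activity and an active Mrc1 locus make the Venus protein and the receptor that lets diphtheria toxin kill them. CD8 T cells specific for ovalbumin and marked with dsRed (CD2dsRed OT-I) were transferred, and tumors were taken 12 days later, with diphtheria toxin given every 2 to 3 days from early on. Live sections of about 160 µm were tagged in 3 zones through an anchor on CD45, a surface protein of immune cells. There were 2 libraries from 1 pool of treated tumors and no replicates. Untreated tumors were not analysed here, so each comparison below is between cell classes or tags within this pool. The gene library held 73016366 UMIs and the tag library 11292096. A total of 4518 barcodes were kept, with a median of 10482 gene UMIs (range 740 to 148714), 2855 genes and 790 tag UMIs. Intervals are 95% intervals, exact except in the comparison stratified by class, and cover counting error only. Cells are not replicates, so no comparison has a replicate check or a p-value.

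The first question was which cells the depleted tumors held. Neutrophil-like barcodes made up 20.7% of the 4518 (Clopper-Pearson interval 19.5 to 21.9%) and monocyte-like barcodes 20.1% (18.9 to 21.3%). The other phagocytes fell into phagocyte cluster 5 with 7.95% (7.17 to 8.77%), phagocyte cluster 6 with 7.81% (7.05 to 8.63%) and a macrophage-like cluster with 5.93% (5.26 to 6.66%). In clusters 5 and 6 monocyte and macrophage markers were both present and neither led, so they are named by number. Conventional dendritic cell-like (DC-like) barcodes made up 3.83% (3.29 to 4.43%), plasmacytoid DC-like (pDC-like) 2.26% (1.84 to 2.73%), migratory DC-like 0.753% (0.522 to 1.05%), CD8 T-like 1.73% (1.37 to 2.15%) and NK-like 0.509% (0.323 to 0.763%). Melanoma-like barcodes made up 2.79% (2.33 to 3.31%) and fibroblast-like barcodes 0.155% (0.0623 to 0.319%), and 9 barcodes stayed unnamed. No cluster carried the names CD4 T, regulatory T or B cell. Clusters in which most barcodes held markers of at least 2 lineages took 25.3% (24.1 to 26.6%), and over all clusters 1337 barcodes (29.6%, 28.3 to 30.9%) were mixed in this sense. Mixed barcodes had a median of 22823 UMIs against 7550 for the others. The rule sets a fixed number of marker UMIs whatever the depth, so deeper barcodes pass it more easily and this gap is in part set by it. Cells were sorted before encapsulation and the gate is not stated, which can set these shares. At a minimum of 1000 genes the neutrophil-like share was 5.21%, since these barcodes had a median of 830 genes, and at leiden resolution 0.5 the macrophage-like share was 9.10%.

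**Figure D1:**
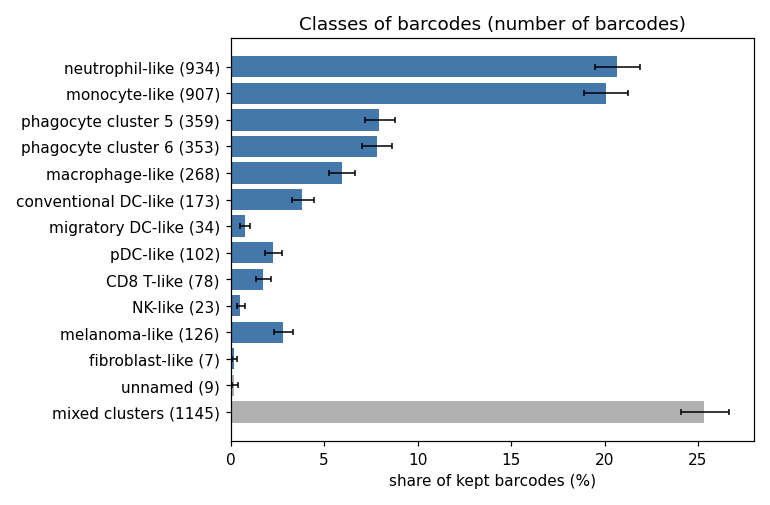
Share of the 4518 kept barcodes in each class, in percent, with exact 95% binomial intervals as error bars and the number of barcodes in brackets. Neutrophil-like (20.7%) and monocyte-like (20.1%) barcodes are the most frequent single classes, and mixed clusters (grey, like the unnamed barcodes) hold 25.3%.

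Mrc1, which encodes the mannose receptor CD206 and carries the depletion receptor in these mice, was highest in phagocyte cluster 6. It had 10.5 UMIs per 10000 there (10.3 to 10.8), 4.95 in phagocyte cluster 5 (4.71 to 5.21), 1.40 in monocyte-like (1.33 to 1.48) and 0.697 in macrophage-like barcodes (0.636 to 0.762). After thinning every barcode to 1000 UMIs, 58.9% of cluster 6 barcodes had an Mrc1 UMI (53.6 to 64.1%), 26.6% of cluster 5 (22.0 to 31.7%), 8.93% of monocyte-like (7.16 to 10.98%) and 4.49% of macrophage-like barcodes (2.34 to 7.72%). In neutrophil-like barcodes, a class that should lack it, the thinned share was 0.538% (0.175 to 1.25%). Without thinning the shares were 92.4% in cluster 6, where barcodes had a median of 17036 UMIs, and 1.61% in neutrophil-like barcodes, with a median of 1977.5 UMIs. Thinning left out 21 barcodes of cluster 5, 1 macrophage-like and 4 neutrophil-like ones, and none of cluster 6. Mrc1 had 1.45 UMIs per 10000 in DC-like (1.33 to 1.59) and 2.41 in migratory DC-like barcodes (2.11 to 2.73), but 0.592 in the latter without mixed barcodes. It had 0.0198 in CD8 T-like barcodes (1 UMI) and none in NK-like barcodes, which allows up to 0.179. Mixed barcodes made up 46.2% of cluster 6, and without them its value was 12.1 and that of macrophage-like barcodes 0.346. The order of the lower classes depended on the clustering: macrophage-like barcodes had 0.795 UMIs per 10000 against 0.667 in monocyte-like ones at a limit of 5% mitochondrial UMIs, and 1.54 against 0.436 with the 1 barcode marked as a doublet kept. At a minimum of 200 genes, cluster 5 had 1.62 against 2.30 in monocyte-like barcodes.

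The series addresses an immune axis between lymphocytes and myeloid cells, for which 7 more genes were followed in every class. Their values are given for part of the classes. Cxcl9 and Cxcl10, interferon-gamma-inducible chemokines that bind CXCR3, were highest among the named classes in macrophage-like barcodes. Cxcl9 had 4.03 UMIs per 10000 there (3.88 to 4.18), 0.529 in phagocyte cluster 6 (0.287 without mixed barcodes), 0.0813 in phagocyte cluster 5, 0.573 in DC-like and 0.0932 in monocyte-like barcodes. Cxcl10 had 3.92 in macrophage-like barcodes (3.78 to 4.07), 1.22 in cluster 6 (0.942 without mixed barcodes), 0.163 in cluster 5, 0.172 in monocyte-like, 0.681 in neutrophil-like and 0.402 in melanoma-like barcodes. Without mixed barcodes macrophage-like values were 2.93 for Cxcl9 and 2.97 for Cxcl10, and in migratory DC-like barcodes Cxcl9 was then 4.48 against 1.35 with them and Cxcl10 0.0740 against 0.461. Thinned shares with a Cxcl9 UMI were 14.2% in macrophage-like (10.3 to 19.0%; 30.6% without thinning) and 0.215% in neutrophil-like barcodes (0.214% without thinning). Xcl1, a chemokine that attracts XCR1-bearing dendritic cells, had 9.16 UMIs per 10000 in NK-like (7.77 to 10.7) and 3.67 in CD8 T-like barcodes (3.16 to 4.23). Its UMIs lay in 87.0% of NK-like but 14.1% of CD8 T-like barcodes (34.8% and 6.41% after thinning). Xcl1 had 0.00200 in monocyte-like barcodes, from 2 UMIs. Ifng, the gene of interferon gamma, had 0.892 in CD8 T-like (0.650 to 1.19) and 0.655 in NK-like barcodes (0.327 to 1.17), and no UMI in neutrophil-like, monocyte-like or macrophage-like barcodes, which allows up to 0.0142, 0.00301 and 0.00434. Flt3l, a growth factor for dendritic cells, had 0.277 in CD8 T-like (0.152 to 0.465) and 0.238 in NK-like barcodes (0.0649 to 0.610, from 4 UMIs). In DC-like barcodes it had 0.0969 (0.0671 to 0.135). Csf1, the macrophage growth factor gene, had 3.52 in neutrophil-like barcodes (3.27 to 3.78), with a thinned share of 22.6%, and 0.0291 in monocyte-like ones. It had 8.47 in the 9 unnamed barcodes (4.63 to 14.2, from 14 UMIs), 1.01 in the 7 fibroblast-like ones (0.677 to 1.45) and 0.421 in cluster 6 (0.164 without mixed barcodes). Cxcr3, the receptor of Cxcl9 and Cxcl10, had 0.705 in pDC-like (0.516 to 0.940), 0.595 in NK-like (0.285 to 1.09) and 0.515 in CD8 T-like barcodes (0.337 to 0.755). Xcl1 in NK-like barcodes was 4.70 at a minimum of 1000 genes, 5.93 at a limit of 20% mitochondrial UMIs and 5.18 at leiden resolution 2. On build mm10, these genes lie at chromosome 2, 14229392 to 14332057 (Mrc1), chromosome 5, 92321347 to 92328079 (Cxcl9) and 92346638 to 92348889 (Cxcl10), and chromosome 1, 164931644 to 164935527 (Xcl1). Ifng lies at chromosome 10, 118441046 to 118445892, Flt3l at chromosome 7, 45129788 to 45136432, Csf1 at chromosome 3, 107741048 to 107760469, and Cxcr3 at chromosome X, 101731535 to 101734269.

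**Figure D2:**
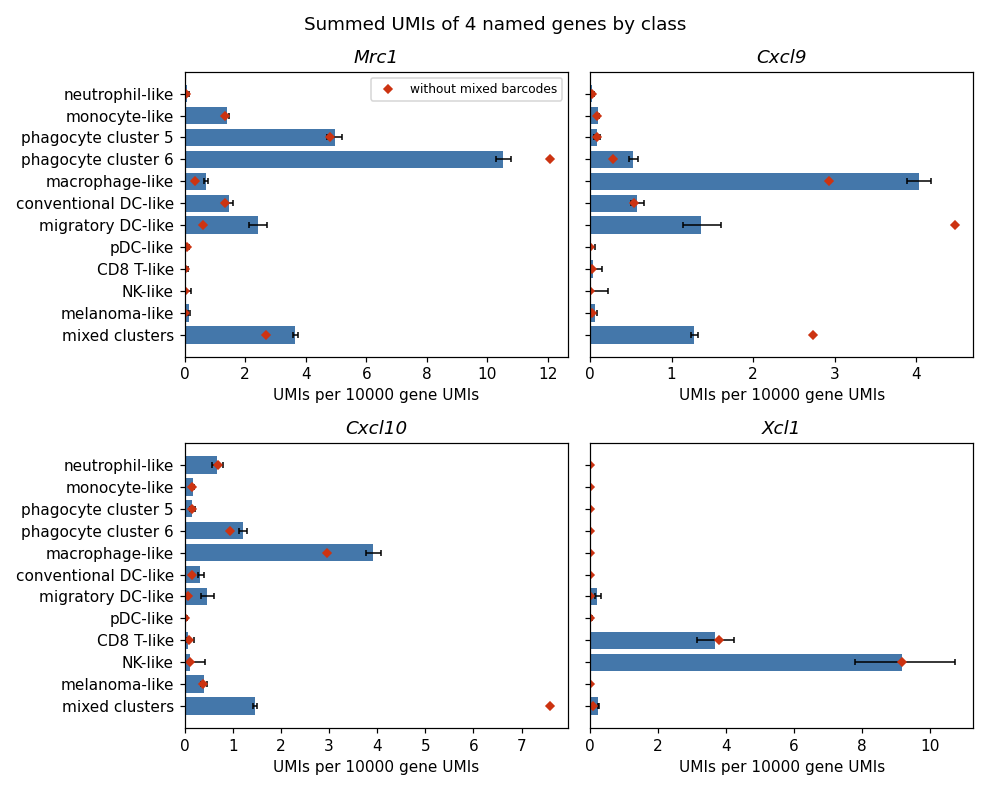
Summed UMIs per 10000 gene UMIs for Mrc1, Cxcl9, Cxcl10 and Xcl1 by class, with exact 95% Poisson intervals as error bars. Diamonds give the value without mixed barcodes: Mrc1 is highest in phagocyte cluster 6 (10.5, and 12.1 without mixed barcodes), and Xcl1 in NK-like barcodes (9.16).

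Macrophage-like against monocyte-like barcodes showed higher interferon response, interferon-gamma-inducible chemokine, major histocompatibility complex (MHC) class II and cell cycle genes, and lower inflammatory cytokine and matrix genes. A list gene is called higher or lower here when it had at least 20 UMIs over both sides, was at least 2-fold apart and its interval excluded 1. Of 18 measured interferon response genes 12 were higher and none lower (median log2 ratio 1.53), among them Ifit3, an antiviral gene, at 28.8-fold (17.7 to 50), and Iigp1, an interferon-induced GTPase, at 40.2-fold (19.2 to 101). All 3 measured interferon-gamma-inducible chemokines were higher (median log2 ratio 4.76), with Cxcl9 at 43.2-fold (35.1 to 53.7). Of 7 MHC class II genes 5 were higher (median log2 ratio 2.35), and of 9 MHC class I genes none was called (0.43). All 16 cell cycle genes were higher (median log2 ratio 5.06): Rrm2, a subunit of ribonucleotide reductase, was 98.4-fold higher (59.3 to 176), Top2a, a topoisomerase of dividing cells, 55.7-fold (43.8 to 72.0), and Mki67 35.7-fold (28.8 to 44.8). Of 9 inflammatory cytokine genes 7 were lower (median log2 ratio -1.73), Il6 at a ratio of 0.120 (0.0138 to 0.484). Of 10 matrix remodelling genes 5 were lower and 1 higher, with Thbs1, which encodes thrombospondin, at 0.0515 (0.0484 to 0.0548); another is Vcan, a marker that helped to name 1 of the monocyte-like clusters. Among 12 recruiting chemokines 6 were lower, such as Ccl6 at 0.0964 (0.0921 to 0.101) and Cxcl3 at 0.0691 (0.0610 to 0.0779; 0.0129 without mixed barcodes), and 3 were higher, with Ccl8, a ligand of CCR8, at 74.7-fold (39.0 to 164). Of 12 lipid-associated macrophage genes 6 were higher, including Trem2, a lipid receptor, and 2 lower. The 10 measured genes of the CD206+ macrophage list split, with Folr2, Cbr2, Stab1 and Gas6 higher and Mrc1, Cd163 and F13a1 lower. Among random lists matched on mean expression the interferon response median lay at percentile 100, and the CD206+ macrophage median (-0.06) at 17.4. Only Folr2 of these 4 stayed higher without mixed barcodes, which made up 26.9% of the macrophage-like class. Of this class 14.6% carried neutrophil and 16.04% melanoma markers. The Mrc1 level was instead above the monocyte-like one at a limit of 5% mitochondrial UMIs and with the marked doublet kept. In all, 64 list genes were higher and 36 lower; the second count was 16 with the marked doublet kept, 17 at leiden resolution 0.5 and 20 at a limit of 20% mitochondrial UMIs. The histone genes Hist1h1a and Hist1h1b, outside the lists, were among the 10 leading genes of the macrophage-like cluster beside C1qa, C1qb and C1qc, so its cell cycle values are in part set by how it was defined.

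Phagocyte clusters 5 and 6 together, against monocyte-like barcodes, showed higher CD206+ macrophage, recruiting chemokine, inflammatory cytokine, MHC class II, lipid-associated and dissociation stress genes. Neutrophil markers moved with them: 46.2% of cluster 6 and 1.11% of cluster 5 barcodes carried these, against 2.05% and 4.67% in the 2 monocyte-like clusters. Cluster 6 held 7031654 gene UMIs and cluster 5 3073262, so cluster 6 weighs more in each ratio. Osm, Vegfa, Ptgs2 and Egr1 were leading genes of cluster 6 only, and Spp1 of cluster 5 only. Mrc1 levels were 10.5 in cluster 6, 4.95 in cluster 5 and 1.40 in monocyte-like barcodes. Csf1 levels were 0.421, 0.0911 and 0.0291 in the same order. The ratios below are for both clusters together and may not hold for each. Of 10 CD206+ macrophage genes 7 were higher (median log2 ratio 2.48), with Folr2, a folate receptor, at 9.59-fold (6.29 to 15.3). Of 12 recruiting chemokines 10 were higher (median log2 ratio 2.23), with Ccl8 at 41.8-fold (21.8 to 92.1) and Cxcl1, a neutrophil attractant, at 7.25-fold (6.06 to 8.72). Of 9 inflammatory cytokine genes 8 were higher (median log2 ratio 2.23), with Il6 at 12.5-fold (8.25 to 19.8; 4.81 without mixed barcodes), Ptgs2, the prostaglandin synthase COX-2, at 8.87-fold (8.22 to 9.57) and Osm, which encodes oncostatin M, at 7.74-fold (7.35 to 8.14). Without mixed barcodes the same 10 chemokines and 8 cytokine genes were higher (median log2 ratios 2.06 and 1.93). Of 12 lipid-associated genes 7 were higher (median log2 ratio 1.21), with Cd36, a fatty acid receptor, at 12.0-fold (10.4 to 13.99) and Mmp12, macrophage elastase, at 28.5-fold (17.6 to 49.4; 14.1 without mixed barcodes). Of 7 MHC class II genes 5 were higher (median log2 ratio 1.74). Of 19 hypoxia and glycolysis genes 5 were higher, Vegfa, an angiogenic growth factor, at 9.24-fold (8.04 to 10.7). Interferon response genes moved little, with 2 of 18 higher, and with none higher and 1 lower without mixed barcodes, but all 3 interferon-gamma-inducible chemokines were higher (median log2 ratio 2.22, and 1.82 without mixed barcodes), with Cxcl9 and Cxcl10 in cluster 5 at the monocyte-like level. Of 16 cell cycle genes 5 were lower, Ube2c at 0.161 (0.108 to 0.234), and Mcm5 was higher. Genes of the dissociation stress list were higher as well, 12 of 13 (median log2 ratio 2.03), with Egr1, an immediate early gene, at 22.6-fold (20.3 to 25.3). Il10, an anti-inflammatory cytokine gene, was 7.94-fold (5.89 to 10.9) and Csf1 11.03-fold higher (7.54 to 16.7), and without mixed barcodes these were 7.28-fold (5.30 to 10.2) and 3.94-fold (2.502 to 6.37). In all, 79 list genes were higher and 8 lower, and 4 lower with the marked doublet kept.

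DC-like against macrophage-like barcodes showed higher MHC class II and costimulation and lower interferon and cell cycle genes. The sides differed in other markers: 0.578% of DC-like and 16.04% of macrophage-like barcodes carried melanoma markers, and 12.7% and 26.9% were mixed. Without mixed barcodes all 7 MHC class II genes stayed higher (median log2 ratio 3.85), and all 16 cell cycle and 9 of 18 interferon response genes lower. All 7 MHC class II genes were higher (median log2 ratio 3.93), H2-Eb1 at 17.5-fold (16.7 to 18.3), Cd74, the invariant chain, at 10.8-fold (10.5 to 10.99), and Ciita, their transcriptional activator, at 15.2-fold (11.4 to 20.7), while of 9 MHC class I genes none was called (0.26). H2-DMb2, an MHC class II gene outside the list, helped to name the DC-like cluster, so its MHC class II values are in part set by how it was defined. Of 8 checkpoint ligand and costimulation genes 5 were higher (median log2 ratio 1.39), with Pdcd1lg2, a ligand of PD-1, at 13.1-fold (3.90 to 69.0), and without mixed barcodes 3 of 7 were (Cd80, Cd86 and Pvr): Pdcd1lg2 then had under 20 UMIs, and Cd274 moved from 2.01-fold (1.66 to 2.43) to 1.99-fold (1.57 to 2.53), below the 2-fold limit. Ccl17, a ligand of CCR4, was 58.5-fold (34.5 to 108) and Itgae, the integrin CD103, 46.6-fold higher (26.3 to 91.3). All 3 interferon-gamma-inducible chemokines were lower, Cxcl10 at 0.0836 (0.0687 to 0.101) and Cxcl9 at 0.142 (0.123 to 0.164), as were 10 of 18 interferon response genes (median log2 ratio -1.23). All 16 cell cycle genes were lower, and Trem2 was at 0.0663 (0.0556 to 0.0785). Of 9 inflammatory cytokine genes 5 were higher, and so were 7 of 13 dissociation stress genes, Egr1 at 13.9-fold (11.8 to 16.4). In all, 51 list genes were higher and 48 lower, with 27 higher at a minimum of 200 genes, 30 at a limit of 20% mitochondrial UMIs and 29 with the marked doublet kept.

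**Figure D3:**
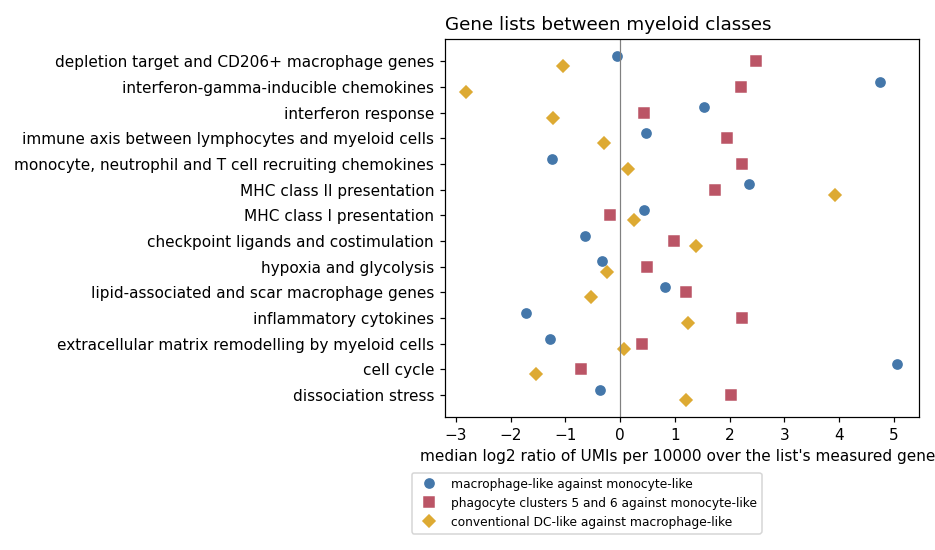
Median log2 ratio of UMIs per 10000 over the measured genes of each myeloid list, for 3 comparisons of classes. In macrophage-like against monocyte-like barcodes the cell cycle (5.06) and interferon-gamma-inducible chemokine medians (4.76) are the highest, and in DC-like against macrophage-like barcodes the MHC class II median (3.93) is.

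CD8 T-like against NK-like barcodes showed higher exhaustion genes and lower memory genes. Of 10 measured exhaustion genes 5 were higher and none lower (median log2 ratio 0.91). Havcr2, the inhibitory receptor TIM-3, was at least 5.88-fold higher against a floor of 3 UMIs in the NK-like class, and Tox, a transcription factor of exhausted T cells, 5.44-fold (2.79 to 12.1). Ctla4, a checkpoint receptor, was 6.19-fold (2.56 to 19.5), Rgs16 13.3-fold (3.57 to 112) and Lag3, also an inhibitory receptor, 32.6-fold higher (5.72 to 1302, with 1 NK-like UMI). Of 8 memory and stem-like genes 6 were lower (median log2 ratio -1.72), with Tcf7, the factor TCF-1, at 0.0951 (0.0375 to 0.214) and Bcl2, a survival factor, at 0.275 (0.174 to 0.432). The granzymes split: Gzmk was 40.9-fold higher (7.21 to 1630, with 1 NK-like UMI) and Gzma at 0.00102 (2.58e-05 to 0.00573, with 1 CD8 T-like UMI). Cxcr6, the receptor of CXCL16, was 21.8-fold (8.42 to 80.6) and Ccl5 3.81-fold higher (3.41 to 4.28), and Xcl1 was at 0.400 (0.321 to 0.499). The CD8 T-like Xcl1 UMIs lay in 14.1% of the barcodes of that class. The NK-like Xcl1 level fell at a minimum of 1000 genes, a limit of 20% mitochondrial UMIs and leiden resolution 2. The Xcl1 ratio may therefore depend on how the NK-like class formed. Of 12 effector genes 4 were higher and 2 lower, of 9 immune axis genes 2 were higher (Ccl5 and Cxcr6) and 2 lower (Xcl1 and Csf2), and of 3 residency genes Cxcr6 was higher and Cd69 lower. Among 10000 random lists matched on mean expression, the exhaustion median lay at percentile 99.95 and the memory median at 0. Of 8 dissociation stress genes Fos, Jun and Zfp36 were lower. In all, 15 list genes were higher and 16 lower between 78 and 23 barcodes. The counts were 23 higher at a minimum of 200 genes, 48 lower at 1000 genes, 67 lower at a limit of 20% mitochondrial UMIs and 74 lower at leiden resolution 2.

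The zones were read from 3 tags named ZC1, ZC2 and ZC5. Which tag marks the outer, mid or inner zone is not stated, so classes are compared by tag. A tag was called in 1419 barcodes (31.4%, 30.1 to 32.8%), namely ZC1 in 1016, ZC2 in 186 and ZC5 in 217. Monocyte-like barcodes and phagocyte clusters 5 and 6 were mostly ZC1, at 82.8% (78.4 to 86.6%), 82.4% (73.6 to 89.2%) and 80.0% of called barcodes (69.6 to 88.1%). Macrophage-like barcodes had 48.7% ZC1 (37.2 to 60.3%) and 39.7% ZC5 (28.8 to 51.5%), and DC-like barcodes 51.7% ZC1 (38.2 to 65.0%) and 32.8% ZC5 (21.01 to 46.3%). Neutrophil-like barcodes had 70.7% ZC1 (65.7 to 75.3%) and 23.6% ZC2 (19.4 to 28.3%). The 37 called CD8 T-like barcodes were spread over the tags, with 40.5% ZC1 (24.8 to 57.9%), 27.0% ZC2 (13.8 to 44.1%) and 32.4% ZC5 (18.0 to 49.8%). Melanoma-like barcodes, which should lack CD45, got a call in 4 of 126 (3.17%, 0.872 to 7.93%), with a median of 94.5 tag UMIs. Over all barcodes, called or not, ZC1 led in 50.7% of monocyte-like (47.4 to 54.0%), 42.2% of neutrophil-like (39.0 to 45.4%) and 35.1% of macrophage-like barcodes (29.4 to 41.1%). With a leading tag at least 1.5 times the second the ZC1 share of called barcodes was 64.0% in monocyte-like and 56.8% in neutrophil-like barcodes, and at 4 times it was 100% and 97.6%.

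**Figure D4:**
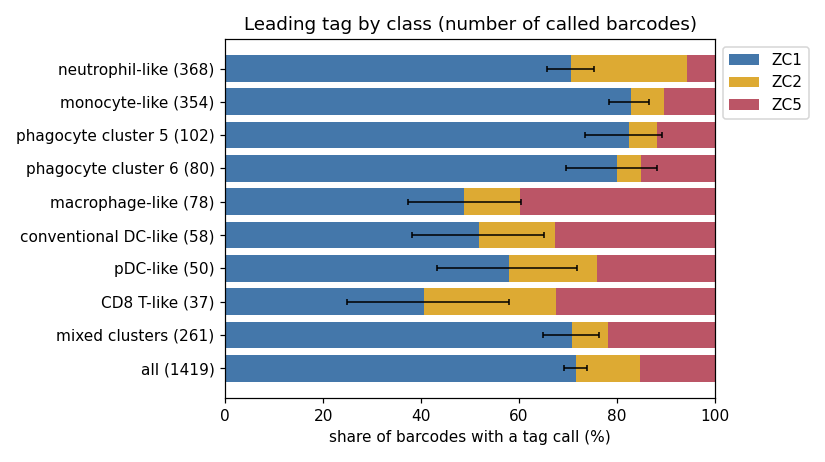
Share of the barcodes with a tag call that ZC1, ZC2 and ZC5 lead in each class, in percent, with exact 95% binomial intervals of the ZC1 share and the number of called barcodes in brackets. ZC1 leads 82.8% of called monocyte-like and 48.7% of called macrophage-like barcodes.

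With a leading tag at least 2 times the second, no class of the planned comparison of zones reached 50 barcodes in both tags. For this reason 2 other tag comparisons were chosen after the data were seen. At 1.5 times, monocyte-like barcodes (375 ZC1 and 130 ZC5) and macrophage-like barcodes (57 and 51) did reach 50. The planned comparison within these classes was not run at that setting. In neutrophil-like barcodes, ZC1 (260 barcodes) against ZC2 (87) showed higher interferon response and stress genes. Of 13 interferon response genes 7 were higher and none lower (median log2 ratio 1.29), with Ifit1 at 5.06-fold (2.25 to 14.1), Rsad2, which encodes viperin, at 2.90-fold (1.51 to 6.22) and Isg15, a ubiquitin-like interferon product, at 2.46-fold (1.80 to 3.42). Cxcl10 was 15.2-fold higher (2.61 to 611, with 1 ZC2 UMI). Of 11 dissociation stress genes 4 were higher, Dusp1, a phosphatase gene, at 2.43-fold (2.07 to 2.85) and Atf3 at 4.12-fold (2.24 to 8.41). Outside the lists, Retnlg, a neutrophil granule gene, was 3.48-fold (2.94 to 4.14) and Ifi47, an interferon-induced GTPase, 7.87-fold higher (2.08 to 66.6). Lower genes were Cxcl1 at 0.163 (0.0700 to 0.360), Spp1, which encodes osteopontin, at 0.393 (0.304 to 0.509), Ifngr1, an interferon gamma receptor chain, at 0.489 (0.374 to 0.643) and Tubb5 at 0.358 (0.151 to 0.871). In all, 17 list genes were higher and 4 lower, but over all 3617 tested genes 74 were higher and 188 lower. Without mixed barcodes (258 against 87) Ccl9, Tap1, Fn1 and Vcan were no longer called higher, and Thbs1 was called lower. The same 7 interferon response and 4 stress genes stayed higher. The list counts were 10 and 7 at a minimum of 1000 genes, 10 and 2 at a limit of 5% mitochondrial UMIs, 1 and 2 with a leading tag at least 4 times the second, where ZC2 held 2 barcodes, and 2 lower at 1.5 times.

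In the pooled monocyte-like, macrophage-like and phagocyte cluster barcodes, ZC1 (479 barcodes) against ZC5 (92) showed lower cell cycle and interferon-gamma-inducible chemokine genes, but the tags differed in class make-up. Macrophage-like barcodes were 38 of the 479 and 31 of the 92. Pooled, all 16 cell cycle genes and all 3 measured interferon-gamma-inducible chemokines were lower, and 7 list genes were higher and 29 lower. The pooled counts were 13 higher at a limit of 20% mitochondrial UMIs, 1 higher and 15 lower with a leading tag at least 1.5 times the second, and 47 higher at 4 times, where ZC5 held 8 macrophage-like, 3 cluster 5 and no other barcodes of these classes. Melanoma markers were in 1.46% of the ZC1 (0.590 to 2.99%) and 8.70% of the ZC5 barcodes (3.83 to 16.4%), and T cell markers in 3 ZC1 and no ZC5 barcodes. Stratified by class, 1 of 16 cell cycle genes was lower, Rrm2 at 0.445 (0.347 to 0.570), and 7 of 171 list genes were higher and 9 lower (5 and 10 without mixed barcodes). Without mixed barcodes Rrm2 was at 0.252 (0.172 to 0.367), Mcm5 was also lower at 0.454 (0.326 to 0.632), and Ube2c was 2.19-fold higher (1.73 to 2.77). With mixed barcodes kept, only Cxcl10 of the 3 chemokines stayed called, at 0.440 (0.367 to 0.528): Cxcl16 was at 0.577 (0.510 to 0.653), and Cxcl9 turned to 1.49 (1.29 to 1.71). The stratified higher genes included Ccl5, a T cell attractant, at 24.2-fold (9.34 to 62.9), Gas6, a ligand that bridges dying cells to phagocytes, at 10.1-fold (3.40 to 30.2) and Il6 at 4.17-fold (1.06 to 16.4). None of these 3 calls held without mixed barcodes, where Ccl5 was 2.86-fold (0.707 to 11.6, from 34 against 3 UMIs) and Il6 2.34-fold higher (0.587 to 9.29), and Gas6 had under 20 UMIs. Rsad2, 2.38-fold higher (1.19 to 4.74), and the stress gene Hspa1b, 3.89-fold (1.77 to 8.56), stayed higher without them, at 7.74-fold (2.26 to 26.5) and 4.12-fold (1.98 to 8.61). The stratified lower genes included Cxcl1 at 0.356 (0.278 to 0.455), Il10 at 0.317 (0.186 to 0.541), Cd163, a scavenger receptor, at 0.426 (0.277 to 0.656) and Cd40 at 0.451 (0.288 to 0.707). Without mixed barcodes Il10 was no longer called, at 0.893 (0.349 to 2.28). Cxcl1 was then at 0.183 (0.123 to 0.270), Cd163 at 0.247 (0.145 to 0.421) and Cd40 at 0.337 (0.185 to 0.616).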

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

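The test of mVenus below was chosen after the result was seen. Transcripts of 3 reporter sequences lie outside the comparisons above and exceeded the limit that a count of 0 allows: mCherry had 12 UMIs in kept barcodes, mVenus 50 and dsredexpress1 5. Of the mCherry UMIs, which mark the tumor line, 10 were in melanoma-like barcodes. All 5 dsredexpress1 UMIs, which mark the transferred T cells, were in 2 mixed barcodes with T cell markers.

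The mVenus UMIs, from the allele that also carries the toxin receptor, lay in 48 barcodes: 13 UMIs were in phagocyte cluster 6, 6 in phagocyte cluster 5, 25 in mixed clusters, 4 in monocyte-like and 2 in DC-like barcodes. Per gene UMI, clusters 5 and 6 had 9.32 times the level of the other classes outside mixed clusters (3.58 to 28.5, from 19 against 6 UMIs), and these clusters also had the highest Mrc1 levels. Free or misassigned RNA alone would give all classes a like level, and this ratio argues against that for the classes compared. The limits are that clusters 5 and 6 were grouped for it after their counts were seen, and that mixed clusters, with 25 of 50 UMIs, were left out. No biological explanation was tested, since untreated tumors were not analysed here. Cells that made the receptor between doses, or that were not killed by a dose, may both be present, and these data hold no value that separates the 2.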

How the results depend on the processing

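Leaving out mixed barcodes, the threshold of 20 marker UMIs, stratification by class and the class comparisons at other leiden resolutions were chosen after the data were seen. Of 290 values under alternatives, 199 stayed within the interval of the reported value, or within 1.5 times for counts, and 91 moved. Of these 91, 65 were among the 221 values for main comparisons and 26 among the other 69, and 44 moved by over 1.5 times. The single pool without replicates limits every comparison, mixed barcodes those of phagocytes and dendritic cells, the 23 NK-like barcodes those with NK-like cells and the low share of tag calls those between tags. In settings that were clustered again, a class can hold other barcodes than before, and the cause of each difference was not tested. No NK-like cluster formed at leiden resolution 0.5 or a limit of 5% mitochondrial UMIs, nor phagocyte cluster 5 at resolution 0.5, so values that need them are missing there.

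At a minimum of 200 genes the shares were 26.8% monocyte-like, 6.83% macrophage-like and 21.01% mixed, Mrc1 was 10.1 in cluster 6 and 1.35 in macrophage-like barcodes, Cxcl9 was 3.63, and 23 list genes were higher in CD8 T-like than NK-like barcodes. At 1000 genes the shares were 5.21% neutrophil-like, 22.3% monocyte-like, 7.44% macrophage-like and 28.7% mixed, Mrc1 was 10.2 and 0.848, Xcl1 in NK-like barcodes was 4.70, 48 list genes were lower in CD8 T-like barcodes, the ZC1 share of neutrophil-like barcodes was 65.1%, and their tag comparison gave 10 genes higher and 7 lower. At a limit of 5% mitochondrial UMIs, Mrc1 and Cxcl9 in macrophage-like barcodes were 0.795 and 3.00, and the neutrophil tag counts 10 and 2. At 20% the shares were 17.04% monocyte-like, 8.92% macrophage-like and 21.5% mixed, Mrc1 and Cxcl9 in macrophage-like barcodes were 1.49 and 3.25, Xcl1 in NK-like barcodes was 5.93, and 20 list genes were lower in macrophage-like than monocyte-like and 67 in CD8 T-like than NK-like barcodes, and 13 higher between phagocyte tags.

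With the 1 marked doublet kept, the shares were 15.03% monocyte-like, 8.19% macrophage-like and 21.5% mixed, Mrc1 was 10.2 in cluster 6 and 1.54 in macrophage-like barcodes, Cxcl9 was 3.56, and 16 list genes were lower in macrophage-like barcodes. At leiden resolution 0.5 the shares were 28.4%, 9.10% and 22.4%, Mrc1 in macrophage-like barcodes was 1.55 and Cxcl9 3.26, and 17 list genes were lower in macrophage-like barcodes; at resolution 2, Xcl1 in NK-like barcodes was 5.18 and 74 list genes were lower in CD8 T-like barcodes. The share of cluster 6 with an Mrc1 UMI was 76.7% at 2000 UMIs and 92.4% without thinning, and that of macrophage-like barcodes with a Cxcl9 UMI 30.6% without thinning; deeper barcodes set these. With a leading tag at least 1.5 times the second, the ZC1 share was 64.0% in monocyte-like and 56.8% in neutrophil-like barcodes, 2 list genes were lower between neutrophil tags, and 1 was higher and 15 lower between phagocyte tags. At 4 times the shares were 100% and 97.6%, with 1 gene higher and 2 lower between neutrophil tags and 47 higher between phagocyte tags. Without mixed barcodes, Mrc1 was 12.1 in cluster 6 and 0.346 in macrophage-like barcodes, and Cxcl9 2.93. Stratified by class, 9 list genes were lower between phagocyte tags, with 10 lower when mixed barcodes were also left out, and at 20 marker UMIs 19.4% of barcodes were mixed.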

Other observations

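The tests of random pairing, free RNA, cells held together and free tags below were chosen after the result was seen, and the others before it. Beyond the comparisons, the CD8 T-like barcodes had 2.48 UMIs per 10000 of Pdcd1, the inhibitory receptor PD-1, and 2.91 of Tox, against 0.00473 of each in neutrophil-like barcodes. Tcf7, a factor of stem-like T cells, had 0.159 in them. Xcr1, the XCL1 receptor of cross-presenting dendritic cells, had 0.547 in DC-like, 0.140 in migratory DC-like and 0.00100 in monocyte-like barcodes, and Cd209a, a marker of the other conventional lineage, 1.23 in DC-like barcodes. Il12b, a subunit of interleukin 12, had 2.88 in migratory DC-like barcodes and no UMI in DC-like ones, and Ccl22 had 2.05 and 0.0941. Il1b, a neutrophil and monocyte cytokine, had 160 in neutrophil-like, 62.6 in phagocyte cluster 6, where 46.2% of barcodes carried neutrophil markers (66.8 without mixed barcodes), and 8.17 in monocyte-like barcodes. Arg1, an arginase of suppressive myeloid cells, had 5.96 in cluster 6, 3.27 in cluster 5 and 1.20 in monocyte-like barcodes. These genes were chosen after their values were seen.

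Most barcodes with T cell markers also carried those of phagocytes: 83.3% of 533 did (79.9 to 86.4%), against 61.4% for the melanoma lineage (55.0 to 67.5%), 51.9% for the neutrophil lineage (49.7 to 54.2%) and 45.4% for the pDC lineage (37.9 to 53.1%). Random pairing of single cells would give like shares. Free RNA would give barcodes with T cell markers no more phagocyte marker UMIs than barcodes under the minimum of genes: over all 533 the median was 79 and the lower quartile 29, while 99% of 69493 barcodes with under 500 genes and at least 10 UMIs had at most 1. The shares argue against random pairing as the whole cause. For free RNA the depths differ widely: the barcodes under 500 genes had a median of 15 gene UMIs. The 444 barcodes with T cell and phagocyte markers had a median of 31227.5. The marker UMIs argue against free RNA as the whole cause only if its amount does not rise with barcode depth, which was not tested. A lower minimum of genes argues against loss of small stand-alone T cells to that minimum. At 200 genes the share was again 83.3%, since of the 170 added barcodes only 6 held a T cell marker UMI, and none more than 1. Loss in the sort or below 200 genes was not tested. No biological explanation was tested against a second group, since the design names none here.

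A hypothesis is that T cells and phagocytes may have been held together before droplets formed. Phagocyte barcodes with 10000 to 40000 UMIs carried neutrophil markers in 39.7% of cases with T cell markers (33.8 to 45.8%) and 34.8% without (32.5 to 37.2%), intervals that overlap. Pairs from the same region would spread the ZC1 to ZC5 log ratio more than random pairs: its SD was 1.01 over 219 barcodes, within the 0.880 to 1.02 of 1000 sets of random pairs. An SD within that range was set beforehand as counting against pairing within regions, so the prediction of such pairing was not met. The SD lay near the upper bound, however, and the random pairs were drawn from stand-alone barcodes, not from the cells in mixed barcodes. The first test does not decide, since its intervals overlap, so the hypothesis of cells held together stays open.

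A further hypothesis is that the T cells in mixed barcodes differ from the stand-alone ones. Per T cell marker UMI, 6 of 21 T cell genes were at least 1.5-fold apart with intervals that exclude 1. The sides were 74 stand-alone barcodes and 349 mixed ones from the cluster that held most barcodes with T cell and phagocyte markers. Higher in mixed barcodes were Gzma at 39.9-fold (7.04 to 1585, with 1 UMI in stand-alone barcodes), Tcf7 at 4.66-fold (2.07 to 12.997), Tbx21 at 3.11-fold (1.14 to 11.9), Eomes at 1.87-fold (1.36 to 2.64) and Ctla4 at 1.66-fold (1.32 to 2.10), and Xcl1 was lower at 0.521 (0.434 to 0.626). The Xcl1 UMIs of CD8 T-like barcodes came from 14.1% of them, and the intervals treat UMIs as independent. Mixed and stand-alone barcodes thus differed in these genes, but this does not decide whether their T cells differ. NK cells, which carry Gzma and Tcf7, may also have entered mixed barcodes, and no test here separates them.

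CD8 T-like barcodes had a ZC1 share of 40.5% of called barcodes (24.8 to 57.9%) against 82.8% for monocyte-like ones (78.4 to 86.6%). The threshold of the call is an unlikely cause, since without it ZC1 led 28.2% of CD8 T-like (18.6 to 39.5%) and 50.7% of monocyte-like barcodes (47.4 to 54.0%). Free tags are too for called barcodes, since 47.4% of CD8 T-like (36.0 to 59.1%) and 3.17% of melanoma-like barcodes (0.872 to 7.93%) got a call. Without the threshold, ZC1 led 22.2% of melanoma-like barcodes (15.3 to 30.5%), which overlaps the CD8 T-like share, so free tags stay open for barcodes without a call. Tag depth stays open: among barcodes with 300 to 1000 tag UMIs, 9 of 15 called CD8 T-like barcodes were ZC1 (60%, 32.3 to 83.7%) against 86.0% of monocyte-like ones (81.2 to 90.0%), and these intervals overlap with few barcodes. A different place of T cells and monocytes in the tumor is a further open explanation, and the unknown zone of each tag keeps it untested.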
